A study of Homo sapiens with 4 samples.

How the data were processed

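RNA was sequenced from 4 libraries of human umbilical vein endothelial cells at passages 3 to 5, of which 2 came from cells infected with Ad-LacZ and 2 from cells infected with Ad-SIRT6 for 48 h. Per the labels' protocols, poly(A) RNA was selected with oligo-dT beads from 100 ng of total RNA, libraries were made with the TruSeq RNA kit V2, which does not mark strand, and single-end reads of 100 nt were sequenced. Per the submitters' processing notes, Trimmomatic 0.32, STAR 2.4.2a and edgeR 3.6.8 were used with the genome build GRCh38.p3. The read counter, the annotation release and any filter on reads are not given in the sources used here. The deposited values are raw counts, whole numbers of reads per gene symbol with no normalization, in 58723 symbols per library. The unit was taken from the values, which sum to different totals of 18459510 to 22786586 per library. Samples were grouped by their titles. The labels do not say whether replicates came from separate cultures or donors, so p-values measure only the spread between these libraries, which may be technical.

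Genes on the Y chromosome, XIST and TSIX (459 symbols) were left out of all tables and tests because the cells came from human donors. Of the symbols in the files, 36658 had the same symbol in GENCODE release 29 (GRCh38), which supplied coordinates, exon overlaps, GC content and gene type. For overlapping genes, reads could not be assigned without knowing strand or the counter's rule, and exons of 55 of the 169 named genes overlapped those of another gene.

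The counts as deposited were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr (minimum count 10, minimum total count 15), libraries were scaled by TMM, and dispersions and the quasi-likelihood test (glmQLFit, glmQLFTest) compared Ad-SIRT6 with Ad-LacZ with no covariate. All adjusted p of single genes are Benjamini-Hochberg values from this test over 14209 genes, with a threshold of 0.05, unless given as adjusted over a list alone. TMM factors were 1.14 and 1.02 in control replicates 1 and 2 and 0.993 and 0.864 in Ad-SIRT6 replicates 1 and 2. CPM are TMM-scaled counts relative to library size, a log2 fold change is Ad-SIRT6 over Ad-LacZ, and its standard error is its size divided by the square root of the F statistic. The biological coefficient of variation was 0.177. Within the control pair 48.3% and within the Ad-SIRT6 pair 55.5% of genes differed in a chi-square test of counts at p under 0.05, so no library was a copy of another.

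The 38 gene lists, the tests, the named-gene rule and the settings to be compared were fixed before the data were examined. Named genes were SIRT6, the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap and whose higher group had a mean of at least 5 CPM, up to 4 passing members per list and direction by smallest p (where none passed, the 2 most abundant), and a fixed set of endothelial and SIRT6-linked genes. Some genes that this rule took are not reported here. The lists covered inflammatory, interferon, metabolic, cell cycle, histone, p53, senescence, repair, antioxidant, stress, heat shock, immediate early, endothelial, vascular, matrix, immune ligand, autophagy, insulin and chromatin genes, other sirtuins, ribosomal and mitochondrial genes, and markers of smooth muscle, fibroblast, leukocyte, epithelial and erythroid cells. Lists with at least 3 tested members were compared with all other genes by camera and tested by fry (limma 3.58.1). Both were adjusted by Benjamini-Hochberg over 37 lists. Camera was run with a preset inter-gene correlation of 0.01 and with an estimated correlation. The estimated form has only the 2 residual degrees of freedom of this design, so a high p from it does not show that a list is unchanged.

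For genes with 0 reads in a group, fold changes are lower bounds against 3 pooled counts. For genes with 1 to 3 reads in a group, ratios of pooled counts carry exact 95% binomial intervals. Shares of single libraries carry exact Clopper-Pearson intervals. The reads have no molecular identifiers, so intervals and floors cover counting error only.

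The procedure was tested on simulated counts of 13716 genes with the control means and the library sizes of these libraries, drawn independently. At each fold 50 genes were changed, besides the heat shock list. The procedure recovered 2% of genes changed 1.5-fold, 48% changed 2-fold, 96% changed 4-fold and 100% changed 8-fold, and 7.59% of its calls were false. The data had 3272 changed genes, and the adjusted threshold is looser where more genes change, so these shares need not carry over. Alternatives were DESeq2 size factors, upper-quartile and total-count scaling, SIRT6 left out of library sizes, no filter, a filter of at least 5 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, a replicate block, each replicate left out in turn, a minimum change of 1.5-fold with glmTreat, an adjusted p under 0.01, an estimated correlation in camera, and fry. With a replicate left out, genes were those of the main filter and the lone library was assumed to vary like the other group. Counts of genes passing in these fits depend on that group's spread, so they do not show that a change came from 1 library.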

Results

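Gene expression was measured by RNA sequencing in human umbilical vein endothelial cells (HUVEC), primary cells from the lining of the umbilical vein. The cultures had been infected for 48 h with an adenovirus carrying SIRT6 (Ad-SIRT6) or with a control adenovirus carrying LacZ (Ad-LacZ), the bacterial gene for beta-galactosidase. SIRT6 is a nuclear NAD-dependent deacylase that acts on histone H3. Each group had 2 libraries. The total counts were 18459510 and 22786586 in control replicates 1 and 2, and 22102045 and 18702705 in Ad-SIRT6 replicates 1 and 2. The comparison of these groups addressed which transcripts of human endothelial cells differ when SIRT6 is overexpressed.

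SIRT6 itself was the most strongly raised transcript in the Ad-SIRT6 cells. Its gene lies on chromosome 19, minus strand, from 4174109 to 4182604 (GRCh38), and its counts were summed over the whole gene. It had 265 and 371 counts in control replicates 1 and 2, against 1468848 and 1801303 in Ad-SIRT6 replicates 1 and 2. These counts were 0.00144% (exact 95% interval 0.00127 to 0.00162) and 0.00163% (0.00147 to 0.00180) of the control libraries. They made up 6.65% (6.64 to 6.66) and 9.64% (9.62 to 9.65) of the Ad-SIRT6 libraries. Mean expression was 14.3 ± 2.3 CPM (SD, n = 2) in controls and 89316 ± 31487 CPM (SD, n = 2) in Ad-SIRT6 cells, a log2 fold change of 12.61 (SE 0.61, edgeR adjusted p = 0.0030). Reads of the cell's own SIRT6 gene and of the viral copy could not be separated.

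Expression differed widely between the groups. In Ad-SIRT6 cells 1809 genes rose and 1463 fell, together 3272 (23.03%) of the 14209 genes tested. The change was at least 2-fold for 951 of the genes that rose and for 703 of those that fell. Heat shock genes, histone genes and ligands of the immune receptor NKG2D were among the strongest rises, and INHBA, BDNF and GDF6, which encode secreted growth factors, were among the strongest falls. The groups did not overlap in 66.1% of tested genes, where chance gives 33.3%. Control libraries correlated at 0.986 and Ad-SIRT6 libraries at 0.983 across genes on the log2 CPM scale, while libraries of different groups correlated at 0.933 to 0.951. The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 5611 genes had an unadjusted p under 0.05. The number of changed genes depended strongly on which library was left out. In such fits the spread came from the other group's pair alone, so these numbers do not show whether single libraries drove the differences. Scaling by total counts alone, which shifted the median log2 fold change of all genes from -0.03 to -0.25, gave 1028 genes higher and 1980 lower, so that 34.2% of calls were higher against 55.3% with TMM scaling. With a replicate block edgeR called 8183 genes, 4041 higher and 4142 lower, though the labels do not say what a replicate number marks.

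**Figure D1:**
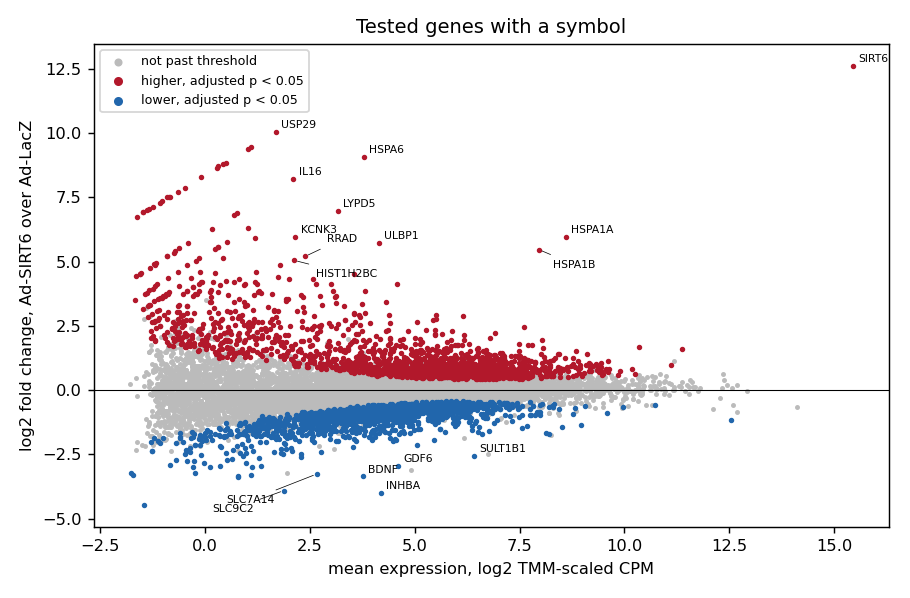
Log2 fold change of each tested gene with a symbol (y axis) against its mean expression in log2 TMM-scaled CPM (x axis). Higher genes are in red, lower genes in blue and the rest in grey. Over all tested genes, plotted or not, 1809 were higher and 1463 lower. Labels mark SIRT6 and most of the genes with the largest changes. SIRT6 lies far from the other genes at 12.61, and the slanted rows of points at low expression are genes with 0 or few control reads, whose fitted fold changes depend on the test's prior count.

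Among genes with at least 5 CPM in the higher group, the 3 largest fitted rises after SIRT6 were in genes with 0 to 2 control reads. Whether USP29 and IL16 rose more than LYPD5, at a fitted 126-fold, is uncertain. Their lower bounds were 93.9 and 67.4. USP29, which encodes a ubiquitin-specific protease (chromosome 19, plus strand, 57119138 to 57131926), had 0 control reads and 242 reads in the Ad-SIRT6 libraries, at least 93.9-fold higher against a floor of 3 pooled counts. HSPA6, an inducible HSP70 gene (chromosome 1, plus strand, 161524540 to 161526910), had 2 control reads against 1026, a ratio of 597 with a 95% counting interval of 165 to 4935. IL16, which encodes a chemoattractant cytokine (chromosome 15, plus strand, 81159575 to 81314058), had 1 control read against 325, a ratio of 378 with a counting interval of 67.4 to 14980. The other rises of this group were LYPD5 at a log2 fold change of 6.97, HSPA1A at 5.97, KCNK3 at 5.95, ULBP1 at 5.73, HSPA1B at 5.47, RRAD at 5.20 and HIST1H2BC at 5.05, with edgeR adjusted p between 0.0030 and 0.010. Of these, 3 had few control reads and fold changes that moved by over 1.5 times with 1 library left out. ULBP1, with 2 and 27 control reads, was at 4.89 without control replicate 1 and 8.41 without control replicate 2, and LYPD5, with 4 and 2, ranged from 6.48 to 7.60. KCNK3 had 0 and 6 control reads and was at 5.05 without control replicate 1, so its size rested on which control was used.

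The largest fall was in INHBA, the gene of the activin beta A subunit (chromosome 7, minus strand, 41667168 to 41705834). It went from 34.3 ± 17 CPM in controls to 2.21 ± 0.99 CPM in Ad-SIRT6 cells (SD, n = 2 each), which is 15.9-fold lower (log2 -3.99, SE 0.49, edgeR adjusted p = 0.0099). BDNF, the gene of brain-derived neurotrophic factor (chromosome 11, minus strand, 27654893 to 27722058), went from 24.5 ± 14 to 2.41 ± 0.44 CPM, 10.2-fold lower. The sulfotransferase gene SULT1B1 went from 146 ± 54 to 24.7 ± 15 CPM, 5.93-fold lower. The remaining falls of this group were SLC9C2 at -3.91, SLC7A14 at -3.27, GDF6 at -2.94, TRO at -2.61, RASSF9 at -2.48, FUZ at -2.47 and SALL2 at -2.44 on the log2 scale, with edgeR adjusted p from 0.0093 to 0.049. With 1 library left out the log2 values ranged from -4.32 (without Ad-SIRT6 replicate 2) to -1.88 (without control replicate 2) for GDF6. They ranged from -4.24 to -1.77 for SALL2 and from -3.59 to -1.94 for RASSF9, each without Ad-SIRT6 replicate 1 and replicate 2 respectively. INHBA reached -3.34, SLC9C2 -3.12 and BDNF -2.60 without control replicate 2, and SULT1B1 reached -3.36 without Ad-SIRT6 replicate 2. Exons of IL16, HSPA1B, BDNF, SLC9C2, SLC7A14, FUZ and SALL2 overlap those of other annotated genes, and the library kit does not mark strand, so some of their reads may belong to the overlapping gene. The same limit holds for other genes named below, among them ICAM1, SOD2, MICA, RAET1E, OAS1, NOS3, SIRT2 and KRT8.

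Heat shock genes, which encode chaperones and their partners, rose together. Of 17 tested members 13 rose, and the list median was 1.02 on the log2 scale. HSPA1A (chromosome 6, plus strand, 31815464 to 31817946) went from 12.2 ± 0.76 to 763 ± 200 CPM and its near-identical neighbour HSPA1B (31827735 to 31830255) from 10.96 ± 0.63 to 485 ± 83 CPM (SD, n = 2 each), and the division of reads between this pair is uncertain. The co-chaperone genes DNAJB1 and BAG3 rose 5.45-fold and 3.11-fold. Adjusted over the list alone, 13 members were higher and 1 was lower. In camera, which compares a list with all other genes, the adjusted p was 1.2e-18 with a preset correlation and 0.797 with an estimated correlation. Without control replicate 2, 3 of the 17 members passed in edgeR and 16 had a log2 fold change above 0, with a camera adjusted p of 7.2e-16 at the preset correlation. Without control replicate 1, 7 passed and 15 were above 0, with a camera adjusted p of 1.6e-15.

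Replication-dependent histone genes rose in 10 of 13 tested cases, with a median of 2.85 on the log2 scale (10 members adjusted over the list alone). The list had 23 members, and those not tested were under the filter, with at most 15 reads in a library. The rise therefore covers the tested members and not the whole class. HIST1H2BD rose from 1.83 ± 0.022 to 26.3 ± 0.43 CPM, HIST1H2AC from 4.85 ± 0.72 to 37.2 ± 0.57 CPM and HIST2H2BE from 3.12 ± 0.44 to 25.0 ± 1.4 CPM (SD, n = 2 each). Transcripts of most such genes lack a poly(A) tail, and the libraries were made from poly(A)-selected RNA. Camera gave this list an adjusted p of 8.8e-14 with the preset correlation and 0.797 with an estimated correlation. Reads of these genes may be shared with close family members, and 4 members passed without control replicate 2 and 6 without control replicate 1.

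NKG2D ligands, stress-induced surface proteins recognised by natural killer cells, rose in 5 of 6 tested cases (5 adjusted over the list alone), with a median of 2.43. ULBP1 went from 0.627 ± 0.75 to 34.6 ± 13 CPM and ULBP2 from 3.38 ± 0.93 to 36.5 ± 5.9 CPM (SD, n = 2 each). MICA rose 2.72-fold and MICB 2.38-fold, with log2 fold changes of 1.44 (SE 0.19, edgeR adjusted p = 0.011) and 1.25 (SE 0.23, edgeR adjusted p = 0.021). RAET1E had 2 control reads against 87, a ratio of 50.6 with a counting interval of 13.6 to 424.5. For these ligands the camera adjusted p was 1.7e-07 with the preset correlation and 0.797 with an estimated correlation. Family members share sequence, so reads between them are uncertain, and 2 members passed without control replicate 2.

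Inflammatory genes under the transcription factor NF-kB moved mostly upward, with 11 of 25 tested members higher, 1 lower and 13 not past the threshold (13 higher and 1 lower adjusted over the list alone). ICAM1, a leukocyte adhesion molecule (chromosome 19, plus strand, 10270835 to 10286615), rose 7.41-fold from 16.9 ± 4.5 to 125 ± 21 CPM (SD, n = 2 each). NFKB2 rose 3.20-fold and IL1A 6.50-fold, and IL1B had 0 control reads against 30, at least 11.6-fold higher against a floor of 3 pooled counts. The adhesion gene SELE rose at a low level, from 0.560 ± 0.12 to 11.4 ± 13 CPM, with a spread in Ad-SIRT6 cells larger than the mean (log2 4.31, SE 1.09, edgeR adjusted p = 0.041). Some other members that rose, not named here, also varied widely between the Ad-SIRT6 libraries. PTGS2, the gene of cyclooxygenase-2, fell 2.4-fold. The chemokine gene CCL2 had 68.2 ± 21 CPM in controls and 76.0 ± 40 CPM in Ad-SIRT6 cells and did not pass (edgeR adjusted p = 0.81), and VCAM1, with at most 10 reads in a library, was under the filter on low counts. The camera adjusted p of the list was 0.00073 with the preset correlation and 0.835 with an estimated correlation. Without control replicate 2 there was 1 member past the threshold, and without control replicate 1 there were 3 higher and 1 lower.

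Antioxidant genes of the NRF2 and thioredoxin systems rose in 10 of 23 tested cases (11 adjusted over the list alone), with a median of 0.47. OSGIN1, a target of NRF2, rose 5.13-fold and the mitochondrial superoxide dismutase gene SOD2 2.77-fold. TXNIP, whose product inhibits thioredoxin, rose 2.12-fold from 184 ± 42 to 391 ± 27 CPM (SD, n = 2 each). The camera adjusted p was 6.3e-05 with the preset correlation and 0.797 with an estimated correlation. In edgeR 0 members passed without control replicate 2, 4 without control replicate 1 and 5 without Ad-SIRT6 replicate 2.

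Senescence and secretory genes included 8 higher and 1 lower of 18 tested members (10 and 2 adjusted over the list alone). The cyclin-dependent kinase inhibitor genes CDKN2B and CDKN1A rose 5.62-fold and 2.07-fold, and TIMP1, an inhibitor of matrix metalloproteinases, rose 2.04-fold, while the insulin-like growth factor binding protein gene IGFBP3 fell 3.20-fold. The camera adjusted p was 0.0067 with the preset correlation, 0.797 with an estimated correlation and 0.126 without control replicate 1. In edgeR 0 members passed without control replicate 2, and 3 were higher and 2 lower without control replicate 1. Genes of cholesterol synthesis and other SREBP-2 targets rose in 5 of 24 tested cases (5 adjusted over the list alone). INSIG1, a sterol-regulated gene whose product retains SREBP in the endoplasmic reticulum, rose 2.24-fold from 35.9 ± 3.2 to 80.7 ± 16 CPM (SD, n = 2 each), and the synthesis enzyme gene DHCR7 rose 2.35-fold. The camera adjusted p of this list was 0.021 with the preset correlation, 0.913 with an estimated correlation, 0.112 without control replicate 1 and 0.313 without Ad-SIRT6 replicate 2. In edgeR 0 members passed without either control replicate, and 13 were higher without Ad-SIRT6 replicate 1.

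Leukocyte markers were the last list past camera, where 2 of 3 tested members rose (2 adjusted over the list alone) and the other 12 listed markers were under the filter. ITGAM, an integrin chain of myeloid cells, had 0 control reads against 48, at least 18.6-fold higher against a floor of 3 pooled counts. LAPTM5, a lysosomal protein gene of blood cells that was already abundant in the controls, rose 1.87-fold from 146 ± 7.0 to 272 ± 24 CPM (SD, n = 2 each). The camera adjusted p was 0.041 with the preset correlation, 0.797 with an estimated correlation, 0.126 without control replicate 1 and 0.0723 without Ad-SIRT6 replicate 2, and 0 members passed in edgeR without control replicate 2 and 1 without control replicate 1. The pan-leukocyte gene PTPRC had at most 2 reads in a library.

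**Figure D2:**
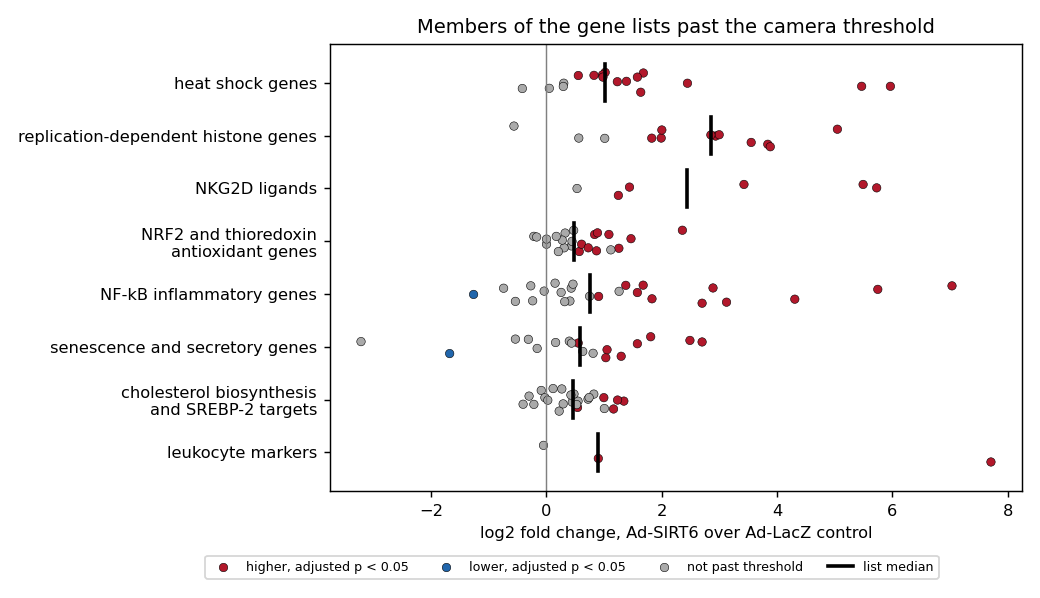
Log2 fold change of each tested member (points, x axis) of the 8 gene lists past the camera threshold with a preset correlation (y axis), in red where higher, blue where lower and grey where not past the edgeR threshold, with vertical bars at list medians; vertical scatter within a list carries no meaning. The medians are highest in histone genes (2.85) and NKG2D ligands (2.43), and PTGS2 and IGFBP3 are the members that fell.

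Genes that mark endothelial function moved in both directions. Over all 14209 tested genes 1809 rose and 1463 fell (23.03% together). Counts near that share, here and in the lists below, do not set a list apart from other genes. KLF2, a flow-induced transcription factor gene (chromosome 19, plus strand, 16324817 to 16327874), rose 3.02-fold from 21.1 ± 2.1 to 63.6 ± 10 CPM (SD, n = 2 each; log2 1.59, SE 0.17, edgeR adjusted p = 0.0086). Of 24 shear-responsive and vasoprotective genes 7 rose and 2 fell (9 and 4 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.0976). GCH1, needed for the nitric oxide synthase cofactor tetrahydrobiopterin, rose 4.69-fold and NOSTRIN, a trafficking protein gene for that synthase, 5.56-fold, while PTGIS, the prostacyclin synthase gene, fell 3.07-fold. EDN1, which encodes the vasoconstrictor endothelin-1, fell 3.20-fold from 425 ± 164 to 133 ± 69 CPM (SD, n = 2 each). NOS3, the endothelial nitric oxide synthase gene, had a log2 difference of 0.80 (SE 0.26, edgeR adjusted p = 0.0753), KLF4 of 0.69 (SE 0.28, edgeR adjusted p = 0.13) and THBD of -0.10 (SE 0.26, edgeR adjusted p = 0.81), none of which passed in this test. Of 30 endothelial identity genes 3 rose and 2 fell (2 and 2 adjusted over the list alone). The surface glycoprotein genes CLEC14A and EMCN fell 2.71-fold and 1.60-fold, and PLVAP, FLT1 and STAB1 rose 1.83-fold, 1.56-fold and 1.48-fold. PECAM1 (log2 -0.03, SE 0.18), CDH5 (0.11, SE 0.18) and VWF (-0.58, SE 0.22) did not pass in this test, with edgeR adjusted p of 0.92, 0.70 and 0.11. NOS3 and VWF passed with DESeq2 and with no filter on low counts, and VWF also with scaling by total counts alone. With a replicate block NOS3, VWF and KLF4 passed, though the labels do not say what a replicate number marks.

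**Figure D3:**
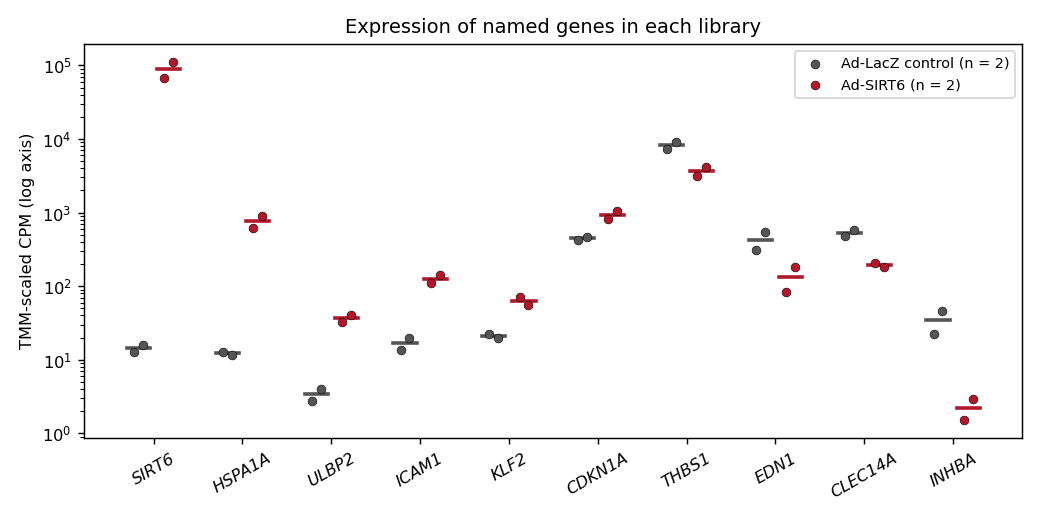
TMM-scaled CPM on a log axis (y axis) of 10 named genes (x axis) in each library, with points for the 2 control libraries in grey and the 2 Ad-SIRT6 libraries in red and horizontal bars at group means. In these genes both Ad-SIRT6 libraries lie on the same side of both controls, from SIRT6 (14.3 against 89316 CPM) to INHBA (34.3 against 2.21 CPM).

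Haemostasis, vessel growth and matrix genes also went both ways. In haemostasis and fibrinolysis 5 of 19 members rose and 3 fell (5 and 3 adjusted over the list alone). Thrombospondin-1, encoded by THBS1 (chromosome 15, plus strand, 39581079 to 39599466), fell 2.24-fold from 8217 ± 1150 to 3673 ± 753 CPM (SD, n = 2 each), and the tissue plasminogen activator gene PLAT rose 2.17-fold. In angiogenesis and Notch signalling 6 of 35 rose and 3 fell (8 and 5 adjusted over the list alone), with ID2 5.75-fold higher and the lymphatic growth factor gene VEGFC 3.71-fold lower. In extracellular matrix and TGF-beta targets 2 of 33 rose and 4 fell (1 and 2 adjusted over the list alone), and the laminin genes LAMA4 and LAMB1 fell 1.59-fold and 1.5-fold. In endothelial-to-mesenchymal transition 3 of 16 rose and 4 fell (3 and 5 adjusted over the list alone), with the actin gene ACTA2 2.26-fold higher and the cadherin gene CDH2 2.65-fold lower. In junction and barrier genes 2 of 24 rose and 2 fell (2 and 2 adjusted over the list alone), among them CLDN11, 2.56-fold lower.

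Stress, growth and repair genes outside these lists changed in part, which was also true of all tested genes (23.03% changed). Targets of p53 included 9 higher and 2 lower of 26 (12 and 3 adjusted over the list alone), with the ferredoxin reductase gene FDXR 2.74-fold and the death receptor gene FAS 2.15-fold higher and BAX 1.69-fold lower, and the list missed the camera threshold (adjusted p = 0.0612). Autophagy and lysosome genes rose in 6 of 23 cases (7 higher and 1 lower adjusted over the list alone), among them the autophagy receptor gene SQSTM1, 2.62-fold higher (camera adjusted p = 0.0528). Insulin, IGF and FOXO genes included 1 higher and 6 lower of 23 (1 and 8 adjusted over the list alone), with the receptor genes INSR and IGF1R 1.92-fold and 1.52-fold lower (camera adjusted p = 0.10). In the unfolded protein and integrated stress responses 5 of 26 rose and 1 fell (7 and 2 adjusted over the list alone), with TRIB3 2.83-fold higher and ATF4 1.53-fold lower. In DNA repair 2 of 32 rose and 4 fell (0 and 3 adjusted over the list alone), and RAD50 and NBN, of the complex that binds DNA breaks, were 2.06-fold and 1.75-fold lower. In G1/S and DNA replication 1 of 29 rose and 2 fell (1 and 2 adjusted over the list alone), with PCNA 2.86-fold higher and CCND1 1.83-fold lower. Immediate early genes rose in 4 of 17 cases (4 adjusted over the list alone), among them ATF3, 4.93-fold higher.

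Interferon-stimulated genes included 6 higher and 3 lower of 36 (6 and 3 adjusted over the list alone), with the antiviral genes OAS1 3.98-fold and IFIT3 3.69-fold higher and IFI44L 4.91-fold and USP18 4.10-fold lower. MHC class I antigen presentation genes rose in 2 of 18 cases (1 adjusted over the list alone), among them the peptide transporter gene TAP1, 2.13-fold higher. In glycolysis and HIF-1 targets 3 of 31 rose and 3 fell (3 and 3 adjusted over the list alone), with NDRG1 4.07-fold higher and the glucose transporter gene SLC2A1 2.33-fold lower, and HIF1A had a log2 difference of 0.09 (SE 0.13, edgeR adjusted p = 0.65). Fatty acid synthesis and SREBP-1 targets rose in 4 of 18 cases (4 adjusted over the list alone). Fatty acid oxidation genes rose in 2 of 18 cases (4 higher and 3 lower adjusted over the list alone). Nuclear-encoded oxidative phosphorylation genes rose in 3 of 34 cases (2 adjusted over the list alone), where 1809 of all 14209 tested genes rose. Ribosome biogenesis and MYC targets rose in 2 of 25 cases (1 adjusted over the list alone), among them BOP1, 2.07-fold higher. Regulators of H3K9 and heterochromatin included 2 higher and 3 lower of 24 (2 and 2 adjusted over the list alone), with HDAC1 1.64-fold higher and DNMT3A 2.23-fold lower. Of the 6 other sirtuins, SIRT7 rose 2.14-fold and SIRT2 1.43-fold (2 higher and 2 lower adjusted over the list alone).

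In the main edgeR test 0 of 45 cytosolic ribosomal protein genes, 0 of 34 G2/M genes and 0 of 13 mitochondrially encoded genes passed. This held over all genes or adjusted over the list alone. At an unadjusted p under 0.05 these lists had 1, 0 and 0 members, and DESeq2 and limma-voom each called 0. EdgeR called 1 ribosomal protein gene with scaling by total counts alone, and 1 ribosomal protein gene and 1 G2/M gene with no filter. With a replicate block it called 20 ribosomal protein, 15 G2/M and 7 mitochondrially encoded genes. The labels do not say what a replicate number marks. RPL3 had a log2 difference of 0.02 (SE 0.21), MKI67 of 0.02 (SE 0.53) and MT-CO1 of 0.19 (SE 0.22). Among markers of other cell types, 1 of 5 smooth muscle and pericyte genes rose and 1 fell (1 and 1 adjusted over the list alone), 1 of 8 fibroblast genes rose (1 higher and 2 lower adjusted over the list alone) and 2 of 4 epithelial genes rose (2 adjusted over the list alone), namely KRT19, 1.94-fold higher, and KRT8, 1.60-fold higher. The erythroid and platelet markers were all under the filter. GATA5 and NKX3-2 had at most 1 read in a library and were not tested.

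Of the 37 lists with a set test, 8 passed camera with a preset correlation and 0 with an estimated correlation. With the latter, 1 list had an unadjusted p under 0.05. The estimated form rests on 2 residual degrees of freedom, so 0 passing lists does not tell whether they shifted. For MHC class I genes the estimated correlation was 0.0126, near the preset, yet the unadjusted camera p went from 0.0246 to 0.158. Among the 8 passing lists the estimate was 0.909 for cholesterol, 0.805 for NKG2D ligand, 0.763 for heat shock, 0.213 for antioxidant and 0.184 for NF-kB genes. It was 0.0800 for histone genes, 0.0502 for senescence genes and -0.260 for leukocyte markers. Where the true correlation is above 0.01, p-values with the preset are too small. With fry, which tests whether the genes of a list move on balance in a common direction, 2 lists passed, the histone genes (adjusted p = 0.0418) and the angiogenesis and Notch genes (adjusted p = 0.0418), and 28 passed for change in either direction. Both of the 2 lists went up in fry. Of the 35 angiogenesis and Notch genes, however, 17 had a log2 fold change above 0 and 18 below, with a median of -0.08. The median and the mean of log2 fold changes differed in sign in the lists of glycolysis, fatty acid oxidation, angiogenesis, haemostasis, and junction genes, and in the last 3 of these camera followed the mean and not the median. Of the 154 called genes that the naming rule took, 18 passed without control replicate 2, 64 without control replicate 1, 134 without Ad-SIRT6 replicate 1 and 124 without Ad-SIRT6 replicate 2, and no called gene among them changed sign in any of these fits. With each replicate left out in turn, the lists of heat shock, histone, NKG2D ligand, antioxidant and NF-kB genes stayed past camera with the preset correlation. Outside the largest rises and falls, some named genes past the edgeR threshold had fold changes that moved by over 1.5 times with 1 library left out. With their log2 ranges, these were SELE (2.05 to 5.17), RAET1E (4.65 to 8.50), ATF3 (1.68 to 3.01), VEGFC (-2.52 to -1.44), EDN1 (-2.35 to -1.22) and IGFBP3 (-2.16 to -0.95). The interferon-stimulated gene OAS2 and the immediate early gene ZFP36 also moved by this much.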

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

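All alternatives were planned. SIRT6 stayed past the threshold in each fit that tested it, with log2 fold changes of 12.18 to 12.94, and no called named gene changed sign in any of them. The count of changed genes (3272, with 1809 higher and 1463 lower) stayed within 1.5 times with DESeq2 size factors (3307), upper-quartile scaling (3362), total counts (3008), SIRT6 left out of scaling (3329), the stricter filter (2699), DESeq2 (3161) and limma-voom (3270). Total counts alone gave 1028 higher. That fit differed from the main one in scaling alone, and it moved the median log2 fold change of all genes from -0.028 to -0.246. Whether this shift accounts for the whole difference was not tested. With no filter on low counts 26952 genes entered the fit and 5047 changed, of which 2486 were lower, and 13 lists passed. A minimum of 1.5-fold with glmTreat left 656 (481 higher, 175 lower), and an adjusted p under 0.01 left 345 (276 higher, 69 lower), as both are stricter by construction.

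Leaving out 1 library gave 80 to 3308 changed genes, 73 to 1823 higher and 7 to 1485 lower, and 7 to 19 lists past camera. The lowest counts came without control replicate 2 (80) and control replicate 1 (646), against 3308 without Ad-SIRT6 replicate 1, so the smaller number of libraries does not account for the drop alone; the cause was not tested. Of the 8 lists past camera, 0 passed with an estimated correlation, a form that rests on 2 residual degrees of freedom. Of all lists fry passed 2, of which 1, the histone genes, was among those 8. The leukocyte list missed the threshold with no filter (adjusted p = 0.0647), DESeq2 (0.0655), limma-voom (0.0739) and the replicate block (0.0903), and could not be tested with the stricter filter; over the settings with the preset correlation its adjusted p ranged from 0.0125 to 0.126, and it was 0.797 with an estimated correlation.

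The replicate numbers are shared between the groups, but the labels do not say that they mark a common culture or day, and there were only 2 pairs. Deviations of same-numbered libraries from their group means correlated at 0.583 across genes. With the replicate block 8183 genes changed, 4041 higher and 4142 lower, no call of a named gene was lost, and 5 of the 14 named genes that had not passed were called (NOS3, KLF4, VWF, MT-CO1 and MT-ND4). In the lists with no member past the unblocked edgeR test with TMM scaling and the filter, 20 ribosomal protein, 15 G2/M and 7 mitochondrially encoded genes were called with it, as were 57 zinc finger genes as higher and 257 as lower. Outside the block, the named genes that had not passed were called 2 at a time with DESeq2 and with no filter (NOS3 and VWF each time), and singly with total counts (VWF) and without Ad-SIRT6 replicate 2 (NOS3).

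Among genes that did not pass, small differences changed sign, and none of these values passed the threshold. With upper-quartile scaling the log2 differences were -0.057 for RPL3, -0.0093 for TOP2A and -0.058 for MKI67. With total counts alone they were -0.088 for CCL2, -0.11 for CDH5, -0.13 for HIF1A, -0.038 for MT-CO1, -0.037 for MT-ND4, -0.20 for RPL3, -0.15 for TOP2A and -0.21 for MKI67, after a shift of all genes to a median of -0.25. With no filter they were -0.017 for RPL3 and -0.0076 for MKI67, and with SIRT6 left out of scaling -0.00048 for MKI67. With 1 library left out the ranges were -0.54 to 0.62 for CCL2, -0.17 to 0.20 for RPL3, -0.47 to 0.18 for THBD, -0.19 to 0.15 for RPLP0, -0.53 to 0.96 for TOP2A, -0.57 to 1.04 for MKI67 and -0.14 to 0.46 for MT-ND4. The cause was not tested. In simulated counts of 13716 genes at this depth and group size, 2% of 1.5-fold changes were recovered. Far fewer genes were changed there than in the data, so this share need not hold for them. Other depths and group sizes were not simulated.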

Other observations

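Of the tests below, those by GC content and expression level, the KRT5 and KRT14 reads, the heat shock count without HSPA1A and HSPA1B, and the search for LacZ were chosen after the result was seen, as were the 3 definitions of the spread tried for the pairs of libraries. The set of zinc finger genes and the keratinocyte list were also made after the main results were seen, and the genes named here were chosen after their values were seen.

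The list of epithelial markers fixed beforehand did not pass camera (adjusted p = 0.474 with the preset correlation and 0.913 with an estimated correlation). Outside it, 6 genes picked after their values were seen rose in Ad-SIRT6 cells. LAMB3, a laminin chain of the epithelial basement membrane, rose from 2.59 ± 0.28 to 45.0 ± 1.1 CPM (SD, n = 2 each; log2 4.12, SE 0.17, edgeR adjusted p = 0.0030), and COL17A1, a hemidesmosome collagen, from 10.7 ± 1.0 to 80.3 ± 15 CPM. The keratin gene KRT15 had a log2 fold change of 3.35, the protease gene KLK6 of 4.13, the motor protein gene MYO5B of 4.53 and the water channel gene AQP3 of 3.65. The integrin gene ITGAX and the GTPase gene RAC2, also picked after their values were seen, rose by 3.48 and 2.21 on the log2 scale, the latter from 43.2 ± 0.96 to 199 ± 4.7 CPM (SD, n = 2 each), while PTPRC and CD74 had at most 2 reads in a library.

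Zinc finger genes, mostly repressors of transcription that bind DNA, leaned downward. Of 488 tested protein-coding genes named ZNF, ZKSCAN, ZSCAN or ZFP, 97 were lower (19.9%) and 27 higher, against 1208 lower (10.4%) and 1623 higher among 11581 other protein-coding genes. The median log2 fold change was -0.48 against 0.01. ZNF532 went from 110 ± 9.0 to 45.9 ± 1.1 CPM and ZNF561 from 81.8 ± 1.2 to 38.8 ± 3.9 CPM (SD, n = 2 each). The camera p was 6.9e-07 with the preset correlation and 0.304 with an estimated correlation. Calls were 1 higher and 0 lower without control replicate 2, 7 and 10 without control replicate 1, 19 and 53 without Ad-SIRT6 replicate 2, and 27 and 146 without Ad-SIRT6 replicate 1. They were 13 and 89 with total counts alone and 34 and 192 with no filter on low counts.

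For the zinc finger genes, GC content and expression level were weighed as technical sources. Within 5 bins of GC content the zinc finger median was lower than that of other genes in each bin, by a mean difference of -0.45 (spread between replicates 0.142), and within 5 bins of expression by -0.32 (spread 0.0861), which argues against either trend as the whole cause. The difference was negative in all 4 pairs of an Ad-SIRT6 and a control library and smallest at -0.27, but the same measure differed by -0.17 between control replicates and by -0.30 between Ad-SIRT6 replicates, a root mean square of 0.245. The bound of 0.1 set beforehand was met by more than the spread under 2 of the 3 definitions tried (0.150 and 0.159, both per library) and by less under the third, which was kept because each value is a difference of 2 libraries, so a shift of a single library cannot be told apart from a group effect. An effect of SIRT6 on these genes stays open as a hypothesis, untested beyond this comparison.

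For LAMB3, COL17A1, KRT15, KLK6, MYO5B and AQP3, keratinocytes in the Ad-SIRT6 cultures were weighed. KRT5 and KRT14, among the most abundant keratinocyte transcripts, together had 0 reads in the Ad-SIRT6 libraries, which was 0% of the 1718 LAMB3 reads and allows at most 0.175%, and this argues against such cells as the source. Of 18 keratinocyte genes 6 were tested and 2 were higher, which decides nothing: DSC3 at a log2 fold change of 3.63 and SFN with 0 control reads against 92, at least 35.7-fold higher against 3 pooled counts. Of these 18 genes 4 (KRT10, DSP, PERP and ITGB4) had over 10 reads in each control library, and 2 (KRT5 and KRT14) were also among the epithelial markers. Other epithelial cell types were not weighed, and transcription of these genes by the endothelial cells stays open as a hypothesis.

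For the heat shock genes, 3 explanations were weighed. Without HSPA1A and HSPA1B, 11 of 15 members were still called higher, which argues against reads shared by this pair as the whole cause. With SIRT6 left out of library sizes and scaling, 13 members were higher. That fit moved the median log2 fold change of all genes only from -0.028 to -0.036, so it could hardly have differed and decides nothing. Scaling by total counts alone gave 12 members higher and 1 lower, so most of these calls did not rest on TMM scaling. A larger load of foreign protein in Ad-SIRT6 than in Ad-LacZ cells cannot be told apart from an effect of SIRT6 activity, because 0 of the counted symbols were LacZ and the control transgene's level was therefore not measured. Without control replicate 2, 3 members of the list were called and 16 of 17 had a log2 fold change above 0.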
